A study of Mus musculus with 6 samples.

How the data were processed

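RNA from 6 cultures of Ba/F3 cells, an established mouse pro-B cell line that needs interleukin-3 to grow, was sequenced after polyA selection with a strand-specific kit, per the labels' protocols. The cells carried an ETV6::FRK fusion gene, which joins the transcription factor gene ETV6 to the tyrosine kinase gene FRK, under a promoter switched on by doxycycline. The group called induced here received 500 ng/ml doxycycline and the group called control received none, with 3 libraries each and RNA taken at 48 h. The labels describe triplicate cultures but do not say whether they came from separate experiments, so p-values measure the spread between these cultures. The titles of the induced libraries carry IL3n and those of the control libraries IL3p. These marks can be read as culture without and with interleukin-3, but the protocols do not say so. If they are, the controls were stimulated by the cytokine and the induced cells were not. Doxycycline, the fusion and whatever the IL3 mark stands for change together, and 0 libraries carry one without the other.

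HISAT2, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions. The counting program and the gene annotation are not given in the sources used here. The deposited table holds raw read counts per gene, whole numbers that total 30970019 to 43177842 per library. It also holds TPM values by the authors, regularised log2 values by the authors, and 6 FPKM columns that were not used here. The authors' deposited comparison gives a signed fold change, the standard error of the log2 fold change, a p-value and a Benjamini-Hochberg adjusted p-value for induced over control. A DESeq2 fit of the counts with the group as its term gave the deposited log2 fold changes within 1.4e-09 and the deposited log2 expression values within 1.3e-08, so that no pairing of replicates had entered the authors' test.

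All 14238 genes of the table have a count of at least 1 in every library. Genes without a read in 1 or more of the libraries were therefore not analysed here, and this leaves out genes that were switched fully on or off. Frk was not analysed here either. The part of the TPM total that is missing from the table came to 0.086%, 0.106% and 0.057% in control replicates 1 to 3 and to 0.584%, 0.356% and 0.112% in induced replicates 1 to 3. Of the gene IDs, 14205 (99.8%) matched the reference gene table of GRCm38.p6, from which chromosome positions were taken. Whether reads were counted by strand, and how reads shared by near-identical genes were treated, is not given in the sources used here. Members of the Gbp, Ifit and Ly6 families, the hemoglobin genes, Csf2rb and Csf2rb2, and Eno1 with its pseudogenes are therefore uncertain as single genes.

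Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test, fixed before the data were examined, was edgeR's quasi-likelihood test with TMM scaling, the low-count filter filterByExpr and Benjamini-Hochberg adjustment over 13260 tested genes, with the group as the only term and a threshold of 0.05. Expression is given as CPM after TMM scaling. A prior count of 2 was added before taking log2 for values per library. DESeq2 was an alternative fixed before the data were examined, and is also the test of the authors' deposited table. A set of 28 gene lists was fixed before the data were examined. Some lists share members, so their results are not independent. Tap1 is in the interferon and antigen presentation lists, and Socs3 in the STAT5 and STAT3 lists. Il4ra is in the STAT3 and receptor lists, Il2ra in the STAT5 and receptor lists, and Icam1 in the STAT3 and NF-kB lists. Fixed members without a row in the table or under the low-count filter were not tested, so the tested members are not always the planned list. Tested were 28 of 28 S phase, 18 of 20 glycolysis, 24 of 30 interferon and 14 of 24 receptor genes. Tested were also 5 of 24 B lineage, 4 of 18 T and NK cell and 3 of 16 fibroblast genes. For each, members were tested with Benjamini-Hochberg adjustment over the list alone, and limma's camera compared the list with all other genes at a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were alternatives.

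Genes were named by a rule fixed before the data were examined. It took both fusion partners, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, and up to 4 called members of each list with a mean of at least 1 CPM. Predicted genes were passed over, and in a list with no called member the rule took the 2 with the highest mean CPM. It also took Cish, Socs2, Pim1, Bcl2l1, Myc, Csf2rb and Il3ra. Because edgeR called 0 genes, the rule was applied to the DESeq2 calls after this had been seen, and the text names fewer genes than the rule allows. Every gene given below with a DESeq2 adjusted p under 0.05 was therefore not called by edgeR adjusted over all genes. Members called over their list alone and outside this rule are named as such.

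The replicate numbers come from the labels and are shared by both groups. The titles of replicates 1 and 2 begin with EF1 and EF2 and those of replicate 3 with EFPC, in both groups. What these prefixes stand for is not given in the sources used here, so replicate 3 may not be the same kind of culture as replicates 1 and 2. Deviations from the group means correlated at 0.17, 0.34 and 0.35 across genes between libraries of the same number, so the numbers were taken to pair the libraries, as every one was over 0.1. Between different numbers they correlated at 0.15 for control 1 with induced 2 and 0.10 for control 2 with induced 1, so replicate 1 was hardly closer to its own number than to replicate 2. They correlated at -0.40 to -0.18 between replicate 3 and another number. Deviations from a group mean cancel out within the group. Likeness of the libraries of replicate 3 alone therefore gives positive values on average among replicates 1 and 2. The value of 0.15 also passes the limit of 0.1, so these correlations do not show that replicates 1 and 2 are paired by number. Values given below within the replicate pairs match libraries by their number only. Genes are not independent replicates in these correlations. A fit with the replicate number as a block was run beside the fit without it. Other alternatives were RLE scaling, library size only, limma-voom, no low-count filter, a mean of at least 1 CPM, a threshold of 0.01, and leaving out each library and each replicate number in turn. Alternatives chosen after seeing the data were edgeR with its newer variance estimate, edgeR with robust estimation, limma-voom with sample weights, limma-voom with the block, DESeq2 with the block and with libraries left out, the DESeq2 calls of named genes and lists with the block, camera with libraries left out, and list medians within each replicate number.

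The tests were tried on simulated counts for 13260 genes, of which 200 changed by known folds between induced and control. With the spread taken from the deposited libraries, edgeR recovered 25.4% of 2-fold, 95.5% of 4-fold and 98.5% of 8-fold changes, with 11 false calls among 157. DESeq2 recovered 64.2%, 98.5% and 98.5%, with 58 false calls among 232. The simulated counts were drawn separately for each gene and library, so no simulated library deviated as a whole, as induced replicate 3 did. The shares recovered therefore do not give the power of either test in the real libraries.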

Results

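Expression profiles were obtained from Ba/F3 cells with and without induction of the ETV6::FRK fusion, to find which pathways the fusion affects. There were 3 induced and 3 control libraries. Total counts were 40179759, 30970019 and 36376467 in control replicates 1 to 3 and 31138705, 40008727 and 43177842 in induced replicates 1 to 3. Depth therefore overlapped between the groups, and the most abundant gene took between 1.05% and 1.56% of the counts in every library. The titles of replicates 1, 2 and 3 begin with EF1, EF2 and EFPC in both groups, so replicate 3 carries another kind of prefix, whose meaning the labels do not give. The comparison is that of induced with control cells, in which doxycycline, the fusion and the IL3 mark of the titles change together.

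Etv6, the mouse gene of the transcription factor partner of the fusion (chromosome 6, 134035700 to 134270158, GRCm38.p6), was higher in the induced libraries. It had 86.2, 81.3 and 94.6 CPM in the controls and 259, 230 and 120 CPM in the induced libraries. The mean rose from 87.3 ± 6.76 to 203 ± 73.3 CPM (SD, n = 3 each), a log2 fold change of 1.23 (SE 0.307) with an adjusted p of 0.00302 by DESeq2 and of 0.153 by edgeR. Whether the fusion transcript adds reads to this gene depends on how closely its sequence matches the mouse gene. Frk was not analysed here.

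Interferon-response genes had the highest median of the 28 lists. Members of the fixed list gave 4 of the 10 largest rises by DESeq2, namely Mx1, Gbp2, Mx2 and Ifit1. The list is not a full set of interferon-response genes, so genes outside it can belong to that response. Of 24 tested members of this list, 22 were higher by edgeR adjusted over the list alone, 22 by DESeq2 adjusted over all genes, and 0 by edgeR adjusted over all genes. The median log2 fold change of the list was 4.21. Mx1, an antiviral GTPase gene (chromosome 16, 97447035 to 97462906, annotated as a transcribed pseudogene), had 0.648, 0.128 and 0.302 CPM in the controls and 415, 194 and 13.4 CPM in the induced libraries, a log2 fold change of 9.19 (SE 1.26, DESeq2 adjusted p = 5.03e-10). Ifit1, which binds foreign RNA, went from 1.27 ± 0.913 to 279 ± 293 CPM (SD, n = 3, DESeq2 adjusted p = 5.59e-05). Gbp2, a guanylate-binding protein gene, went from 1.22 ± 0.830 to 317 ± 325 CPM (DESeq2 adjusted p = 8.20e-06). The 10 largest rises by DESeq2 included Ly6a, which encodes the surface antigen Sca-1 (chromosome 15, 74994877 to 74998031), at 0.197 ± 0.0900 CPM in the controls and 1118, 494 and 6.44 CPM in the induced libraries (DESeq2 adjusted p = 7.59e-11). Iigp1, an immunity-related GTPase gene, and Mpeg1, which encodes a pore-forming protein of phagocytes, were also among them, with log2 fold changes of 10.52 and 8.38 by DESeq2. So were Gbp2b, Gbp4 and Gbp6, of the same gene family as Gbp2 but outside the fixed list, with 9.14, 8.405 and 7.13.

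The rise was far from even across the induced libraries. The median log2 difference of the interferon list from the control mean was 5.11, 4.35 and 0.45 in induced replicates 1 to 3, against 0.10, 0.27 and -0.37 in the controls. The list took 1.11%, 0.647% and 0.113% of the counts in the induced libraries and 0.0965%, 0.124% and 0.0704% in the controls. In induced replicate 3, 13 of the 24 genes lay above all 3 controls, where chance gives 6 on average. The genes of this list are not independent (estimated correlation 0.96), so this count is not a test. Against the control of the same replicate number the list's median was 5.04, 3.93 and 1.09, with 24, 24 and 23 of the 24 genes higher. The list passed camera with an adjusted p of 2.48e-22, and the adjusted p was 0.70 with an estimated correlation. Limma-voom called 0 of the 24 over the list alone, and the edgeR count was 0 without replicate 2 of both groups.

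**Figure D1:**
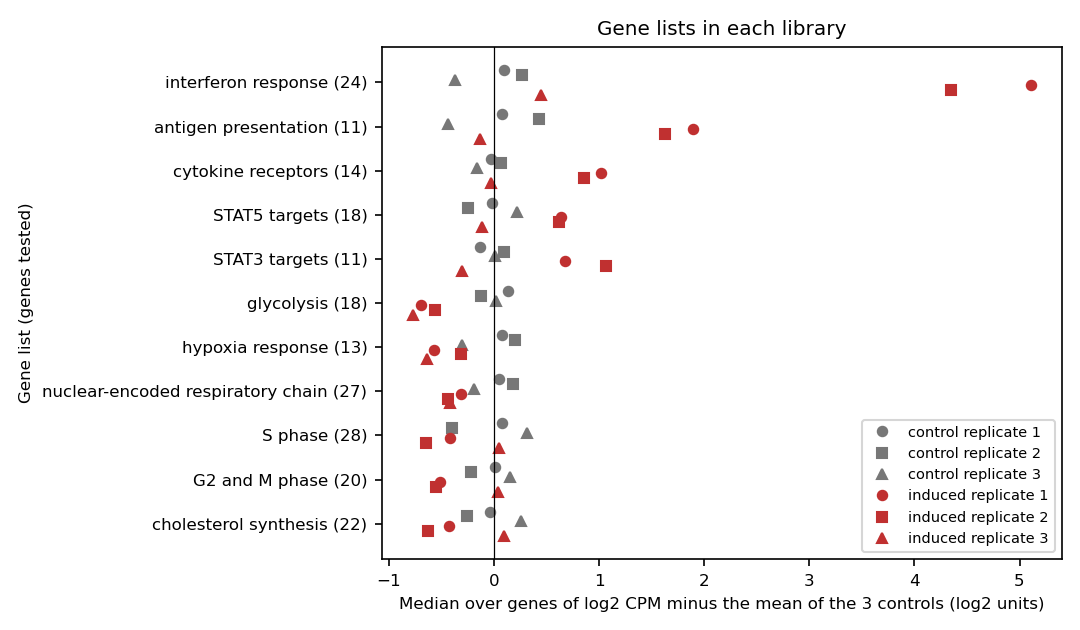
Median over the tested genes of each list of the log2 CPM minus the mean of the 3 controls (x axis, log2 units), with 1 point per library; grey points are controls, red points are induced, and the shape gives the replicate number. The interferon list lies at 5.11 and 4.35 in induced replicates 1 and 2 and at 0.45 in induced replicate 3, while the glycolysis list lies between -0.77 and -0.56 in all 3 induced libraries.

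Antigen presentation genes were higher in part. Of 11 tested members of this list, which holds genes of MHC class I and class II, 5 were higher by edgeR adjusted over the list alone and 5 by DESeq2, and the list's median log2 fold change was 1.30. Nlrc5, the transcriptional activator of MHC class I genes, went from 16.0 ± 2.76 to 175 ± 127 CPM (SD, n = 3), a log2 fold change of 3.47 (SE 0.559, DESeq2 adjusted p = 3.31e-07). Tapbp and Tap1, which load and carry peptides, and B2m, the light chain of MHC class I, had log2 fold changes of 2.08, 1.73 and 1.61 by DESeq2. The following members lie outside the naming rule and were chosen after their values were seen. The class I heavy chain gene H2-K1 was the other called member, with a log2 fold change of 1.46. The class I genes H2-D1 and Tap2 did not pass, with log2 fold changes of 1.32 and 0.45 (DESeq2 adjusted p = 0.0684 and 0.598), nor did the class II pathway genes Cd74, H2-DMa and H2-DMb1, with 0.77, -0.12 and -0.22 by DESeq2. With the replicate block in DESeq2 the call of Tapbp was lost (adjusted p = 0.115) and H2-D1 passed (adjusted p = 0.0011). The list's median was 1.89, 1.63 and -0.13 in induced replicates 1 to 3 against the control mean, and 1.85, 1.10 and 0.50 against the control of the same number. Its camera adjusted p was 0.00290, 0.0764 without control replicate 3 and 0.74 with an estimated correlation. The edgeR count over the list alone was 1 with limma-voom or with a minimum mean of 1 CPM, 1 without induced replicate 1 or 2, 8 without induced replicate 3, and 0 when any of the 3 controls was left out.

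Glycolytic genes were lower in all 3 induced libraries. Of 18 tested members, 11 fell by edgeR adjusted over the list alone and 11 by DESeq2, 0 by edgeR over all genes, and none rose in these tests. The median log2 fold change was -0.69, and the median in each induced library was -0.69, -0.56 and -0.77, against 0.13, -0.12 and 0.02 in the controls. Against the control of the same replicate number it was -0.86, -0.48 and -0.65. Eno1, which encodes an enolase (chromosome 4, 150236708 to 150248879), fell from 1132 ± 178 to 535 ± 46.0 CPM (SD, n = 3), a log2 fold change of -1.07 (SE 0.193, DESeq2 adjusted p = 8.35e-06). Pkm, which encodes the pyruvate kinase of the last step (chromosome 9, 59656576 to 59679372), fell from 2034 ± 231 to 997 ± 114 CPM (log2 fold change -1.01, SE 0.181, DESeq2 adjusted p = 6.09e-06). Hk3, a hexokinase gene, and Pfkl, a phosphofructokinase gene, had log2 fold changes of -1.14 and -0.92 by DESeq2. The hexokinase genes Hk1 and Hk2, outside the naming rule and named after their values were seen, did not pass and had positive edgeR log2 fold changes of 0.43 and 0.57. The list's camera adjusted p was 1.39e-09 and was 0.63 with an estimated correlation. The edgeR count over the list alone was 7 without control replicate 1 and 0 without replicate 1 of both groups.

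Hypoxia-response genes fell in part. Of 13 tested members, 5 were lower by edgeR adjusted over the list alone and 4 by DESeq2, with a list median of -0.37, and of -0.50, -0.51 and -0.37 within the replicate pairs. Bnip3, a mitophagy receptor gene, fell from 115 ± 41.3 to 39.1 ± 17.6 CPM (SD, n = 3, DESeq2 adjusted p = 0.00328). Pdk1, whose product inhibits pyruvate dehydrogenase, fell from 46.5 ± 6.26 to 23.2 ± 2.72 CPM (DESeq2 adjusted p = 6.42e-05). Egln1, which encodes an oxygen sensor, and Ankrd37 had log2 fold changes of -0.98 by DESeq2 and -2.01 by edgeR, in that order. The camera adjusted p was 3.52e-04 and was 0.70 with an estimated correlation. The edgeR count over the list alone was 2 without control replicate 2 and 0 without replicate 1 of both groups.

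Nuclear genes of the respiratory chain had small negative values. All 27 tested members had a negative log2 fold change, with a median of -0.39, and 3 passed DESeq2 while 0 passed edgeR adjusted over the list alone. The 3 were Ndufa4, Uqcrfs1 and Sdhd, which encode respiratory-chain components or assembly partners, with log2 fold changes of -0.72, -0.65 and -0.52. With the replicate block DESeq2 called 5, adding Cox7c and Atp5o, which encode parts of complexes IV and V and were chosen after their values were seen. The list medians were -0.31, -0.44 and -0.42 in the induced libraries and 0.05, 0.18 and -0.19 in the controls, and -0.36, -0.60 and -0.23 within the replicate pairs. The camera adjusted p was 2.21e-07 and was 0.70 with an estimated correlation. Without control replicate 3, edgeR called 17 of the 27 over the list alone, and without induced replicate 3 it called 3. The 13 mitochondrially encoded transcripts had a median of 0.05, 0 calls and a camera adjusted p of 0.794. Their medians within the replicate pairs were -0.38, -0.06 and 0.47, with 0, 6 and 13 of the 13 higher, so the median of 0.05 joins opposite shifts.

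**Figure D2:**
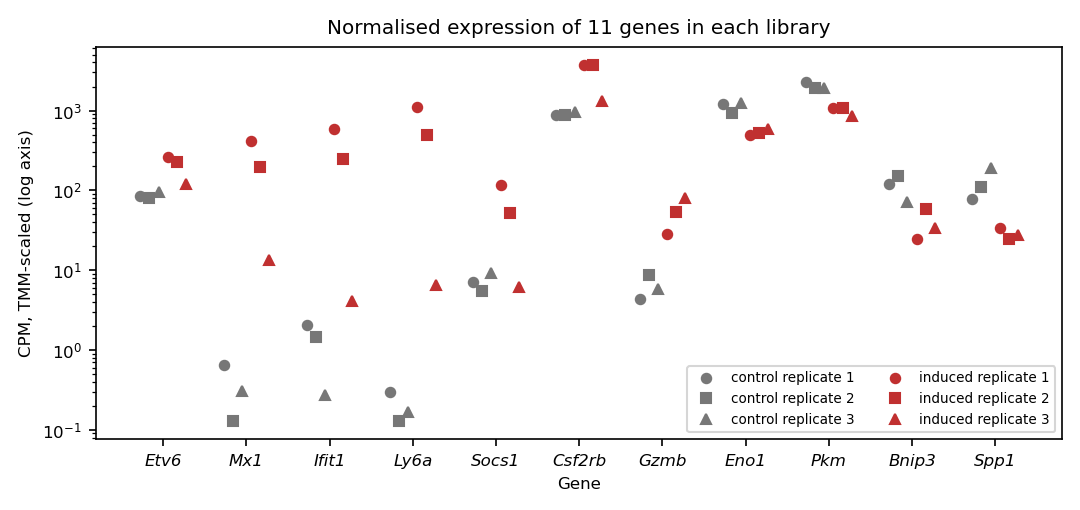
CPM after TMM scaling (y axis, log scale) of 11 genes, with 1 point per library; grey points are controls, red points are induced, and the shape gives the replicate number. Mx1 lies at 415 and 194 CPM in induced replicates 1 and 2 and at 13.4 CPM in induced replicate 3, while Eno1 lies at 493, 529 and 584 CPM in the induced libraries against 1207, 929 and 1259 CPM in the controls.

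Cytokine signalling genes moved in part. Of 18 tested STAT5 targets, 5 were higher and 1 lower by edgeR adjusted over the list alone, and the same counts, 5 and 1, came from DESeq2. The cytokine gene Osm went from 18.5 ± 2.98 to 88.5 ± 47.9 CPM (SD, n = 3, DESeq2 adjusted p = 3.06e-05), and Lif from 25.7 ± 3.82 to 126 ± 94.7 CPM (DESeq2 adjusted p = 0.00189). Socs1 and Socs3, feedback inhibitors of cytokine receptors, had log2 fold changes of 3.03 and 2.24 by DESeq2, and Socs1 had 117, 52.0 and 6.15 CPM in the induced libraries against 7.26 ± 1.93 CPM in the controls. The kinase gene Pim2 was higher and Id1, an inhibitor of differentiation, was lower in the same tests, with edgeR log2 fold changes of 1.85 and -0.92. These 2 genes lie outside the naming rule. With the replicate block DESeq2 left 2 higher and 1 lower, and the calls of Socs1, Lif and Pim2 were lost (DESeq2 adjusted p = 0.144, 0.0806 and 0.0964). Other targets fixed in advance did not pass either test. Cish had 64.1 ± 26.7 CPM in the controls and 99.7 ± 57.9 CPM in the induced libraries, Pim1 700 ± 81.3 and 985 ± 285 CPM, Socs2 54.6 ± 5.83 and 49.5 ± 3.19 CPM, Bcl2l1 106 ± 27.2 and 61.3 ± 19.6 CPM, and Myc 289 ± 24.3 and 301 ± 71.7 CPM. Interleukin-3 itself drives STAT5 targets, and the titles carry IL3p for the controls and IL3n for the induced libraries, so the controls may be cytokine-stimulated cells, which the protocols do not state. The list's median was 0.37, and 0.64, 0.62 and -0.11 in induced replicates 1 to 3, or 0.63, 0.57 and -0.20 within the pairs. The camera adjusted p was 0.0122, 0.0547 with the replicate block, 0.129 without control replicate 2, 0.136 without induced replicate 1 and 0.74 with an estimated correlation. Without induced replicate 3 the median was 0.605, and the block left 2 members past the threshold over the list alone in edgeR. That count was 2 with limma-voom, 0 without control replicate 1 or induced replicate 2, and 11 without induced replicate 3.

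Of 14 tested cytokine receptor genes, 3 were higher by edgeR adjusted over the list alone and 3 by DESeq2, namely Csf2rb, Csf2rb2 and Il4ra. Csf2rb, the beta chain shared by the receptors for interleukin-3, interleukin-5 and GM-CSF (chromosome 15, 78325800 to 78351001), had 886, 888 and 947 CPM in the controls and 3692, 3740 and 1306 CPM in the induced libraries, a log2 fold change of 1.70 (SE 0.381, DESeq2 adjusted p = 6.76e-04). Its neighbour Csf2rb2, a close copy that can share its reads, had a log2 fold change of 1.69 (SE 0.352, DESeq2 adjusted p = 1.79e-04). Il4ra rose from 112 ± 13.9 to 359 ± 144 CPM (SD, n = 3, DESeq2 adjusted p = 4.04e-05). By edgeR over all genes the adjusted p was 0.156 for Csf2rb, 0.146 for Csf2rb2 and 0.136 for Il4ra. Il3ra, the interleukin-3 alpha chain, had 38.5 ± 14.8 and 44.1 ± 6.09 CPM and did not pass. With the replicate block DESeq2 called the same 3 receptor genes higher and 1 lower, Ifngr2, which was chosen after its values were seen. The receptor list's median was 1.0, and 1.02, 0.86 and -0.03 in induced replicates 1 to 3, or 1.05, 0.45 and 0.16 against the control of the same number. Its camera adjusted p was 0.00306, against 0.0706 without control replicate 3 and 0.70 with an estimated correlation, and the median was 0.536 and 0.563 without induced replicate 1 or 2. Of 11 STAT3 targets, 2 were higher by edgeR over the list alone, 1 with the replicate block, and 3 by DESeq2, namely Socs3, Il4ra and the adhesion molecule gene Icam1. Their median was 0.87, and 0.68, 1.07 and -0.30 in induced replicates 1 to 3, or 0.67, 0.94 and -0.04 within the pairs. The camera adjusted p was 0.00745, against 0.0784 without control replicate 3 and 0.74 with an estimated correlation, and the median was 0.39 without induced replicate 1 and 0.325 without replicate 1 of both groups. The edgeR counts over the list alone were 0 for both lists when any of the 3 controls was left out. They were 1 and 1 without induced replicate 2 and 9 and 5 without induced replicate 3, for receptors and STAT3 targets in turn.

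Proliferation and sterol lists shifted down by camera at its preset correlation, without called members in edgeR. The S phase list of 28 genes had a median of -0.37 and the G2 and M phase list of 20 genes a median of -0.32, with 26 and 18 negative values and 0 members past the threshold in edgeR or DESeq2. Their camera adjusted p values were 7.61e-04 and 0.00218, and both were 0.74 with an estimated correlation. That correlation was 0.77 for S phase, 0.65 for G2 and M phase and 0.68 for the cholesterol list, against the preset 0.01. Of the 10 divisions of the libraries into 3 and 3, 5 passed at least 12 lists in camera, the real one included. Against the control mean, the S phase median was -0.42, -0.65 and 0.05 in induced replicates 1 to 3 and 0.08, -0.40 and 0.32 in the controls. Against the control of the same replicate number, the medians were -0.50, -0.25 and -0.28 for S phase and -0.52, -0.53 and -0.07 for G2 and M phase. They were of 1 sign in all 3 pairs, as were those of FOXO targets, p53 targets and monocyte and neutrophil markers, which camera did not pass. In pairs 1 to 3, 1, 3 and 6 of the 20 G2 and M phase genes were higher. Of 22 cholesterol synthesis genes, 2 fell by DESeq2, Pmvk and Fdps of the mevalonate pathway, with log2 fold changes of -0.79 and -0.54. The list's median was -0.35, and -0.48, -0.36 and -0.27 within the pairs, and its camera adjusted p was 7.61e-04, against 0.74 with an estimated correlation. Without control replicate 3 the camera adjusted p was 0.181, 0.0706 and 0.123 for the S phase, G2 and M phase and cholesterol lists, with medians of -0.175, -0.225 and -0.147. Without induced replicate 2 it was 0.067 for G2 and M phase, and the medians of the 3 lists were -0.195, -0.168 and -0.181. With the replicate block, edgeR called 4 S phase and 4 cholesterol genes over the list alone, and DESeq2 called 7 S phase, 1 G2 and M phase and 6 cholesterol genes, all lower. Without induced replicate 3 edgeR called 4 S phase, 13 G2 and M phase and 8 cholesterol genes, and the medians of the last 2 lists were -0.513 and -0.547.

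Among markers of other blood cells, Gzmb, a granule protease gene of cytotoxic and mast cells (chromosome 14, 56258836 to 56262334), rose in all 3 induced libraries. It had 4.34, 8.70 and 5.79 CPM in the controls and 28.4, 52.8 and 79.7 CPM in the induced libraries, a log2 fold change of 3.11 (SE 0.412, DESeq2 adjusted p = 9.09e-11). By edgeR over all genes its adjusted p was 0.127. Of 11 tested mast cell and basophil markers, Gzmb was the 1 that passed edgeR over the list alone, 2 passed with the replicate block, and DESeq2 also called Hdc, the histamine-forming enzyme gene, with a log2 fold change of 1.76. The list's median was 0.43, and 0.69, 0.41 and 0.46 within the replicate pairs, and its camera adjusted p was 0.00306, against 0.0706 without control replicate 3 and 0.70 with an estimated correlation. With single libraries left out the median lay between 0.402 and 0.754, and without induced replicate 3 edgeR called 5 members over the list alone. Without control replicate 3 the camera adjusted p of 7 lists came to lie over 0.05. These were the STAT3, receptor, S phase, G2 and M phase, cholesterol, antigen presentation and mast cell lists, and 6 lists passed in all.

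Spp1, Cxcr2, Aldh3a1 and C3 were among the 10 largest falls by DESeq2. Spp1, which encodes osteopontin (chromosome 5, 104435111 to 104441053), fell from 127 ± 58.5 to 28.6 ± 4.78 CPM (SD, n = 3), a log2 fold change of -2.13 (SE 0.350, DESeq2 adjusted p = 5.04e-07). Cxcr2, a chemokine receptor gene, fell from 42.1 ± 23.0 to 9.70 ± 3.16 CPM (DESeq2 adjusted p = 9.10e-05). Aldh3a1, an aldehyde dehydrogenase gene, and the complement gene C3 had log2 fold changes of -1.85 and -2.12 by DESeq2. None of the 4 passed edgeR over all genes, with adjusted p values of 0.127 for Spp1, 0.14 for Cxcr2, 0.127 for Aldh3a1 and 0.228 for C3.

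The other 16 lists had camera adjusted p values of 0.143 or more. Within them, Cblb, a ubiquitin ligase gene that restrains tyrosine kinases, rose with a log2 fold change of 0.65 (DESeq2 adjusted p = 0.00542) and was the 1 of 10 SRC-family kinases and regulators called over the list alone, with 0 under the replicate block. The cytokine gene Il6 rose from 11.8 ± 0.660 to 56.1 ± 41.0 CPM (SD, n = 3, DESeq2 adjusted p = 5.09e-04). It was the 1 of 12 NF-kB targets called over the list alone, with 2 under the block. Adgre1, a macrophage marker, fell with a log2 fold change of -1.29 (DESeq2 adjusted p = 0.00570) and was the 1 of 8 monocyte and neutrophil markers called. The calls of Cblb, Il6 and Adgre1 over their lists alone were each lost when any of the 3 controls was left out. DESeq2 also called Cited2 lower and Bcl2l11 higher among 13 FOXO targets, with log2 fold changes of -0.74 and 0.54, and Bcl2l11 is also the called member of the 14 BCL2 family genes. It called Sel1l higher among 16 unfolded protein response genes and Aen among 18 p53 targets, with log2 fold changes of 0.71 and 0.77.

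Medians of these lists ran from -0.51 to 0.55. They were 0.17 for 21 ERK feedback genes, 0.20 for FOXO targets, 0.17 for SRC-family kinases and regulators, -0.04 for 29 MYC and ribosome biogenesis genes, 0.03 for the unfolded protein response, 0.34 for p53 targets and 0.17 for the BCL2 family. They were -0.51 for 5 B lineage genes, -0.13 for the monocyte and neutrophil markers, 0.55 for 4 T and NK cell genes, -0.38 for 3 fibroblast genes and -0.20 for 25 cytosolic ribosomal protein genes. In 3 lists the median, the mean and the test differed in sign. The median and mean were 0.03 and 0.19 for 22 amino acid response genes, -0.10 and 0.06 for the NF-kB targets and 0.19 and 0.37 for 10 erythroid and megakaryocyte genes, and camera gave the direction down for all 3. Several of these medians rested on single libraries. Without induced replicate 1 the median was 0.064 for p53 targets and 0.028 for the BCL2 family, which had 0.267 without control replicate 2 and 0.287 without induced replicate 3. That of FOXO targets was 0.392 without control replicate 2 and 0.087 without control replicate 3 or induced replicate 2. The B lineage median was -0.287 without control replicate 2 and the T and NK cell median 0.292 without induced replicate 2. The fibroblast median was -0.053, -0.151 and -0.131 without control replicate 2, induced replicate 1 or induced replicate 2, and -0.863 without induced replicate 3. With 1 library left out, camera passed 5 of the 16 lists in at least 1 of the fits. These were the cytosolic ribosomal proteins without control replicate 3 or induced replicate 2 (adjusted p = 3.59e-04 and 0.0153), the amino acid response without induced replicate 1 or 3 (0.041 and 9.96e-04), the NF-kB targets without induced replicate 1 (0.0403), and the ERK feedback and fibroblast genes without induced replicate 3 (0.00381 and 0.00491). With the replicate block, edgeR called 4 FOXO targets over the list alone and 1 gene each of the p53, B lineage and T and NK cell lists, against 0 without it. In DESeq2 the block added calls in 11 of the 16 lists, and the genes named here were chosen after their values were seen. Higher with the block were, among others, Irs2 among FOXO targets, Ptprc among SRC-family kinases and regulators, Trp53inp1 and Btg2 among p53 targets, Bcl2 of the BCL2 family, Spred3 of the ERK feedback genes, Ikzf1 of the B lineage genes and Lat of the T and NK cell genes. Lower with the block were Npm1 of the MYC list, Ddit4 of the amino acid response, Nfkbia of the NF-kB targets and S100a4 of the fibroblast genes.

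Across all 13260 tested genes, edgeR called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.127. Unadjusted p values were under 0.05 for 2329 genes, where independent p values with no effect give 663. Other divisions of the 6 libraries into 3 and 3 gave 48 to 2099 such genes, with 2099 for control replicates 1 and 3 and induced replicate 3 against the rest, and 965, 880 and 874 for the next 3. DESeq2, as in the authors' deposited table, called 906 genes, 558 higher and 348 lower, of which 440 changed at least 2-fold. With the replicate block in DESeq2, 569 genes were lower. Of the 906, 903 were tested in edgeR, and all 903 had the same sign there, as fits of the same libraries with the same group term would give. The groups did not overlap for 24.1% of all tested genes, where chance gives 10%. They did not overlap for 811 of the 903 called genes. A call for a group difference favours such genes, so this count is no separate support for the calls. Limma-voom called 0 genes, with 2201 at an unadjusted p under 0.05.

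Induced replicate 3, 1 of the 2 libraries with the EFPC prefix, stood apart from the other induced libraries. Across genes its log2 CPM correlated most with control replicate 3, the other EFPC library (Pearson r 0.974), and at 0.947 and 0.952 with induced replicates 1 and 2, which correlated with each other at 0.988. Genes are not independent replicates in these correlations. On the first principal component, which held 48.8% of the variance, induced replicates 1 and 2 lay at 58.2 and 53, induced replicate 3 at -28.9 and the controls at -22.1, -19.1 and -41.2. Without induced replicate 3, edgeR called 892 genes and DESeq2 2160. Of the 892, 494 were among the 906 genes of the full DESeq2 fit, all in the same direction, which fits that share libraries favour. DESeq2 called 245 and 557 genes without control replicate 1 or 2, 1398 without control replicate 3, and 346 and 317 without induced replicate 1 or 2.

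**Figure D3:**
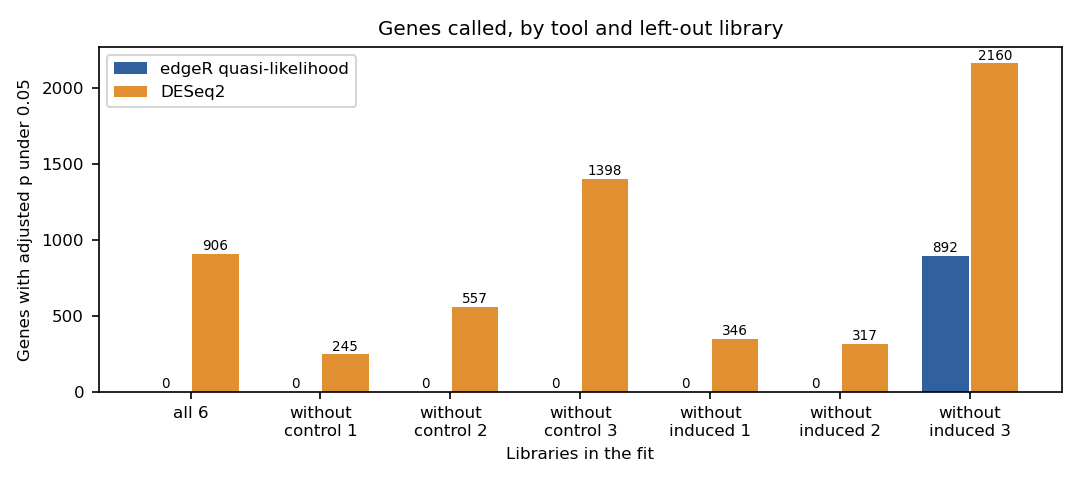
Number of genes with an adjusted p under 0.05 (y axis) in edgeR's quasi-likelihood test and in DESeq2, with all 6 libraries and with each library left out in turn (x axis). The edgeR bars are at 0 except without induced replicate 3, where the count is 892, and the DESeq2 bars run from 245 to 2160.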

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

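Sample weights, the block in limma-voom and DESeq2, and libraries left out of DESeq2 and camera were chosen after seeing the data. The scalings, filters and thresholds fixed in advance left the edgeR count at 0 genes. Other counts of genes changed, higher, lower and at least 2-fold were 906, 558, 348 and 440 with DESeq2, and 4618, 2245, 2373 and 974 with limma-voom and sample weights. In edgeR, leaving out libraries or replicate numbers gave 0 to 2144 changed, 0 to 1300 higher, 0 to 844 lower and 0 to 884 at least 2-fold. The counts above 0 came without induced replicate 3 (892, of them 619 higher, 273 lower and 547 at least 2-fold) and without replicate 3 of both groups. In DESeq2 with libraries left out, the ranges were 60 to 2742, 43 to 1666, 17 to 1076 and 60 to 907. At a threshold of 0.01, DESeq2 called 412 genes, 266 higher, 146 lower and 269 at least 2-fold. The replicate block gave 0 genes in edgeR, and 1339 with 569 lower in DESeq2. In edgeR, the block moved no count of list members by over 1.5 times beyond those given beside the lists. In DESeq2, 812 of the 906 genes were called with the block as well, all in the same direction, 94 were lost and 527 gained, and named genes whose call changed and list counts that moved by over 1.5 times are given beside their lists. With the block in limma-voom, camera also passed the cytosolic ribosomal proteins. The weights of limma-voom were 9.37, 0.50 and 0.44 for the controls and 1.55, 1.48 and 0.21 for the induced libraries.

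Camera passed 12 lists, 6 to 16 with libraries left out, 10 with limma-voom, and 0 with an estimated correlation or the directional test of fry. The mixed test of fry, which ignores direction, was not counted. It gave an adjusted p of 0.0028 for glycolysis, and of 0.05 after rounding for the hypoxia and mast cell lists. The first principal component held 66.6% of the variance over the 500 most variable genes. The amino acid response median turned to -0.170 with limma-voom, -0.101 with the replicate block in edgeR and -0.112 with limma-voom and the block. With sample weights, the medians turned to -0.222 for mitochondrially encoded transcripts, 0.144 for NF-kB targets and -1.074 for the erythroid list. With libraries left out, medians that changed sign ran from -0.222 to 0.447 (amino acid response), -0.042 to 0.153 (unfolded protein response), -0.592 to 0.366 (NF-kB), -0.35 to 0.113 (monocyte and neutrophil), -0.397 to 0.087 (cytosolic ribosomal proteins), -0.179 to 0.141 (MYC), -0.273 to 0.267 (mitochondrially encoded), -0.052 to 0.479 (ERK feedback), -0.034 to 0.241 (SRC family) and -0.869 to 0.558 (erythroid). Myc ran from -0.101 to 0.227 and Il3ra from -0.017 to 0.57. The cause was not tested for any of these. Depth of 30970019 to 43177842 counts limits the values of genes near 1 CPM.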

Other observations

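Induced replicate 3 also differed from the other induced libraries in gene groups and genes outside the interferon lists, given here as values without a test. Against the control mean, the median of the amino acid response list (ATF4 targets) was 0.50, 0.58 and -1.36 in induced replicates 1 to 3. That of the ERK feedback list was 0.49, 0.26 and -0.93, and that of the NF-kB list 0.66, -0.04 and -1.11. Control replicate 3 itself lay at -0.50, 0.01 and -0.19 in these 3 lists. Within the replicate pairs the medians were 0.24, 0.17 and -0.77 for the amino acid response, 0.33, 0.59 and -0.85 for ERK feedback and 0.68, -0.33 and -0.88 for NF-kB. The following genes were chosen after their values were seen. Ddit3, a stress-response transcription factor gene of the ATF4 list, had 87.3, 83.6 and 4.28 CPM in the induced libraries and 25.8, 53 and 5.57 CPM in the controls, so that control replicate 3 was low as well. S100a4, a calcium-binding protein gene, had 1.29, 0.530 and 151 CPM in the induced libraries against 45.9, 83.3 and 124 CPM in the controls. Hba-a1, an alpha-globin gene, had 52.4, 37.0 and 583 CPM against 149, 24.8 and 155 CPM, and Hbb-bs, a beta-globin gene, had 13.1, 25.4 and 388 CPM against 70.8, 2.65 and 77.9 CPM. Ifngr1, the interferon-gamma receptor gene, had 36.5, 48.4 and 159 CPM against 31.9, 39.7 and 27.5 CPM.

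All tests in this part except the correction for GC content and transcript length were chosen after the results they weigh had been seen, as were all limits on CPM and fold in them, of which 1 set was tried. The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 906 genes in DESeq2, the highest other 593, which set control replicates 1 and 3 with induced replicate 3 against the rest, and 1 of the 10 gave as many. In edgeR all 10 gave 0 genes, the highest other included, and at an unadjusted p under 0.05 the real division gave 2329 genes and the highest other 2099. In camera the real division passed 12 lists and the highest other 19, and 5 of the 10 passed as many. Among the 4 divisions that part all 3 replicate pairs, the real one gave 906 genes in DESeq2 and the others 82, 1 and 0, and 593 came from a division that parts 1 pair.

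The interferon list was far lower in induced replicate 3 than in induced replicates 1 and 2. A control library under the wrong label was weighed by glycolysis. The glycolysis median in induced replicate 3 was -0.77, outside the range of the controls (-0.12 to 0.13), although this library correlated most with control replicate 3 (r 0.974). This does not settle the label, because induced replicate 3 also left the control range where it did not follow the other induced libraries. The amino acid response median was -1.36 there, against 0.50 and 0.58 in induced replicates 1 and 2 and -0.50 to 0.30 in the controls. A mixture of induced and control cells at 1 share, in a library without other differences, is argued against. Induced replicate 3 reached 0.9% of the interferon change of induced replicates 1 and 2 (quartiles 0.3 and 3.1). It reached 100.7% of the change of the 11 glycolysis genes that moved at least 1.5-fold (quartiles 55.4 and 112.5), a difference of 99.8 percentage points. With controls of the same replicate number as the baseline, the shares were 1.7% (quartiles 1.1 and 4.4) and 67.7% (13 genes, quartiles 49.8 and 98.7). A lower amount of fusion transcript may contribute and stays open, as does a different source of the cells in replicate 3, whose titles carry another prefix in both groups, which was not tested. Etv6 and the interferon list rank the 3 induced libraries alike, which chance gives with a probability of 0.167, and induced replicate 3 reached 20.9% of the Etv6 change.

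The glycolysis list was lower in all 3 induced libraries. Counts taken up by interferon genes are argued against as the cause, because the list was also lower in induced replicate 3, where these genes were scarce. Its median in induced replicates 3 and 1 was -0.77 and -0.69 against the control mean, a ratio of 1.12, but -0.65 and -0.86 against controls of the same number, where the difference in induced replicate 3 was the smaller one. GC content and transcript length as the whole cause are argued against, because the median went from -0.69 to -0.65 after a loess correction (quartiles -0.88 and -0.41). The condition marked IL3 in the titles and the fusion cannot be told apart, since 0 libraries carry one without the other, so a change driven by the fusion, by doxycycline or by that condition remains a hypothesis.

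Genes nearly silent in the controls had a low level in induced replicate 3. They include Mx1, Mx2, Ifit1 and Gbp2 of the interferon list, so this is not separate from the small share reached by that list. The 18 genes under 2 CPM in the controls and at least 50 CPM on average in induced replicates 1 and 2 reached a median of 0.91% of the rise seen in those libraries (quartiles 0.76% and 1.37%, a ratio of 1.8, with -0.42% for Gbp11 and 4.28% for Mx1), or 1.13% with control replicate 3 as the baseline (quartiles 0.80% and 1.54%, a ratio of 1.93). Their median level, as a share of that in induced replicates 1 and 2, was 0.513%, 0.331% and 0.089% in control replicates 1 to 3 against 1.217% in induced replicate 3. Only genes with at least 1 read in every library were analysed. Some reads in the controls and in induced replicate 3 were therefore given beforehand and are no finding. Quartiles this close are what a small carry-over of material from those libraries at 1 share may leave, but single genes spread more widely. Mx1 had 13.4 CPM in induced replicate 3 and Ly6a 6.44 CPM (a share of 0.77%), although Ly6a was the higher of these genes in induced replicates 1 and 2. Carry-over at 1 share therefore does not account for all 18 genes. A small fraction of responding cells or a low level of the genes' own expression predicts close quartiles as well and was not tested apart. For 136 genes that the controls express the median share was 1.36% with quartiles of -5.74% and 10.93%, which by the limit first set would have counted for carry-over and was taken as open once the quartiles had been seen to span 0.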
